A study of Xenopus laevis with 12 samples.

How the data were processed

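RNA from dissected Xenopus laevis hindlimbs was measured on 12 Agilent 2-colour arrays, 3 in each of 4 groups. Per the labels, hindlimb RNA was labelled with Cy3 and a common reference RNA with Cy5 on every array, with no dye swap, so a dye effect of a probe stays in its ratio and cancels only in differences between groups. The scanner files are spot intensity values, made with Agilent Feature Extraction A.7.5.1 per the file headers. The submitters' processing notes name the same software without a version. The deposited series table holds log10 ratios. On each array they differed from the negative of the scanner software's log ratio by at most 0.005, so they are log10 of Cy3 over Cy5 with no further centring, with array medians from -0.0197 to 0. No deposited ratio exceeds 2 in absolute value, a bound that 235 values of 42 probes reach, so larger ratios were cut there. The scale and direction of that table were thereby settled, and it was used as an alternative.

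Each array held 22575 features, of which 1080 were controls and 21495 were probes of 60 bases. Mean foreground and median local background intensities were corrected with normexp at an offset of 50, which pulls the ratios of dim probes towards 0 and so understates their fold changes. Log ratios were normalised by loess within each array, with control spots at weight 0. This centres the ratios of each array near 0, so a shift of most probes in the same direction could not be seen. The balance of higher and lower calls rests on this centring. Spots that the scanner software marked as outliers in either channel were left out, 40 to 177 per array, and saturated spots were kept. Values are given as log2 of hindlimb over reference, with positive values for more signal in the hindlimb. Probes were tested if they were well above background in Cy3 on all 3 arrays of at least 1 group, which held for 19972 probes. Median Cy3 intensity above background lay between 60.9 and 142 per array and median Cy5 intensity between 115 and 156. Between 87.8% and 95.6% of probes were well above background in Cy3. The number of arrays limits the precision of each value.

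The 4 group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05 over the probes tested in each comparison. There were 5 comparisons, namely TRDN 2 weeks minus NF55 control, TRDN 6 weeks minus NF66 control, TRDN 6 weeks minus TRDN 2 weeks, NF66 control minus NF55 control, and the difference of the first 2. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The labels give all groups the replicate numbers 1 to 3 without saying what a number shares. Deviations from the group means of same-numbered NF55 control and TRDN 2 weeks arrays correlated at 0.35, 0.202 and 0.324 across probes. Those of arrays with different numbers correlated at -0.334 to 0.13. In each of the other 5 pairs of groups at least 1 of the 3 same-numbered correlations was under 0.1. Arrays with different numbers could also match, as TRDN 6 weeks arrays 1, 2 and 3 correlated at 0.367, 0.44 and 0.262 with NF66 control arrays 3, 1 and 2. The correlations therefore do not establish that the numbers pair NF55 control and TRDN 2 weeks arrays. The fit was tested on simulated data for TRDN 6 weeks minus NF66 control, with 200 of 19972 probes changed. Of 50 probes changed 2-fold, 100% were recovered, and of 50 changed by 0.5 on the log2 scale, 64%. There were 4 false calls. The simulated values had independent normal errors with the spread that the fit had estimated, and they bypassed background correction and loess. The simulation therefore tested the fit alone and not the processing before it.

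No gene names are given here. The scanner files pair probes with sequence accessions and probe sequences, and 0 of 21399 accessions were found in the reference gene table of assembly Xenopus_laevis_v10.1, which lists 44456 genes. That table holds RefSeq accessions and 0 of those on the array have the RefSeq form, so the identifiers do not match in kind and nothing follows about which genes the array holds. The 14 gene lists and 8 marker lists fixed before the data were examined were therefore not tested, and the thyroid hormone receptor genes could not be looked up. The rule for named genes was kept except for its gene symbol and for the number named, which the rule had set higher for every comparison. For each comparison the text names the 2 probes with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05 that were well above background in Cy3 on all arrays of the higher group and, for a difference of 2 groups, had no overlap between the groups' values. Probe names join an accession and a position. A probe that the rule selects is not reported here, and no other was named in its place.

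The alternatives were the scanner software's processed signals, no background subtraction, a normexp offset of 0, median centring, Aquantile after loess, Cy3 alone, the series table, 3 other filters on dim probes, the replicate number as a block over all arrays and, chosen after seeing the data, in the paired groups alone, only the groups compared, eBayes with trend and robust, array weights, other thresholds, and leaving out each array. Every array was on its own slide, 12 in all, so no slide held more than 1 array and a block for slide could not be fitted. The scanner software extracted the values of all 12 images on 1 day, so that day gave no batches to compare. Scan batches were not examined.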

Results

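The study profiled hindlimbs of Xenopus laevis, a frog whose limbs grow and remodel during metamorphosis under thyroid hormone. Transgenic tadpoles carried a dominant negative thyroid hormone receptor (TRDN), a receptor form that blocks the response to the hormone, which doxycycline switched on from a muscle-specific promoter. Hindlimbs were taken after 2 or 6 weeks of doxycycline at 50 µg, a mass for which no volume is given. The labels list stage NF55 for both TRDN groups. Nontransgenic siblings at stage NF55 treated for 2 weeks were the age-matched control of the 2-week group, and juvenile frogs at stage NF66 were the endpoint control of the 6-week group. The labels list 2 weeks of doxycycline for the juveniles too. Each of the 4 groups had 3 arrays. No nontransgenic group of the age of the 6-week tadpoles was included, so at 6 weeks the effects of the transgene, of age, of stage and of the length of doxycycline treatment could not be separated.

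TRDN 6 weeks and NF66 control stood apart along the main axis of variation, while NF55 control and TRDN 2 weeks overlapped. The first principal component held 73.9% of the variance over 19411 probes and placed NF55 control at -34.4 ± 4.4, TRDN 2 weeks at -36.4 ± 4.3, TRDN 6 weeks at 7.0 ± 3.4 and NF66 control at 63.8 ± 4.9 (mean score ± SD, n = 3). The second held 13.8% and set TRDN 6 weeks, at 30.2 ± 1.9, apart from NF55 control at -11.3 ± 2.8, TRDN 2 weeks at -6.2 ± 0.5 and NF66 control at -12.7 ± 3.0. Across probes, arrays of the NF55 control and TRDN 2 weeks groups correlated at r = 0.942 to 0.982, which overlapped the range within the NF55 control group, 0.948 to 0.989. TRDN 6 weeks arrays correlated with NF66 control arrays at 0.587 to 0.724, with TRDN 2 weeks arrays at 0.773 to 0.827 and with NF55 control arrays at 0.768 to 0.824.

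**Figure D1:**
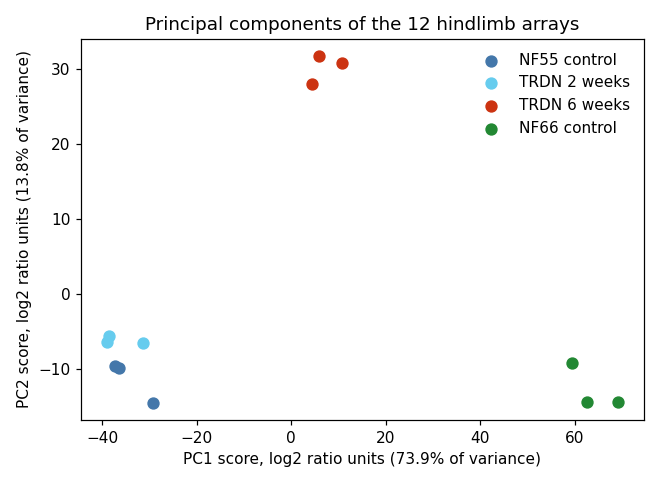
Scores of the 12 arrays on the first and second principal components of log2 hindlimb over reference ratios, one point per array, coloured by group. TRDN 2 weeks arrays sit beside NF55 control on the first component, and TRDN 6 weeks arrays, with a mean of 7.0, lie between them and NF66 control at 63.8.

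After 2 weeks the TRDN hindlimbs differed from those of their nontransgenic siblings at few probes. Probe BC053823_1347 (sequence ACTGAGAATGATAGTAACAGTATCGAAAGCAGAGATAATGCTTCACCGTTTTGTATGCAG) went from 0.87 ± 0.17 in NF55 control to -1.45 ± 0.19 in TRDN 2 weeks (log2 ratio, mean ± SD, n = 3), a change of -2.32 (SE 0.13, limma adjusted p = 4.03e-05). It was at -1.44 ± 0.12 in TRDN 6 weeks and at -0.28 ± 0.20 in NF66 control. Probe CD255184_153 (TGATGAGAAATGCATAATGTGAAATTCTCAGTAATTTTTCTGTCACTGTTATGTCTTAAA) changed by -2.39 (SE 0.13, limma adjusted p = 0.000226). From 2 to 6 weeks it rose by 1.81 (SE 0.13, limma adjusted p = 2.71e-05), to -0.95 ± 0.03. Of the NF66 arrays 1 had a value, 1.84, so no test against NF66 control is given. The largest rises were smaller. Probe BX850589_599 (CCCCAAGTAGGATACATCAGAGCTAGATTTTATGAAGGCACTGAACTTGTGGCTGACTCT) rose by 1.06 (SE 0.10, limma adjusted p = 0.00205) and reached 2.47 ± 0.21 at 6 weeks, against 0.82 ± 0.07 in NF66 control. Probe AF157558_1879 rose by 1.08 (SE 0.19) with a limma adjusted p of 0.0474, a call that was lost when any 1 of the 3 NF55 control arrays or of the 3 TRDN 2 weeks arrays was left out, with the adjusted p at most 0.202 over all alternatives. With the replicate number as a block in these 2 groups, its limma adjusted p was 0.0625. It fell by 2.25 from 2 to 6 weeks (SE 0.19, limma adjusted p = 1.72e-05) and at 6 weeks differed by 0.23 from NF66 control (SE 0.19, limma adjusted p = 0.342).

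In all, 65 of 19941 probes changed at 2 weeks, 22 higher and 43 lower, and 1198 had an unadjusted limma p under 0.05. With no effect a share of 0.05 of the probes would be expected to have such a p, and 1198 is not far above that share. The balance turned with array weights, to 149 higher and 120 lower, and without the NF55 control and TRDN 2 weeks arrays numbered 3, to 13 and 11. All other settings kept more lower than higher probes. Of the 43 lowered probes, 21 fell at least 2-fold, and of these 18 were also lowered at 6 weeks against NF66 control. Of the 21, 13 were higher and 7 lower in NF66 than in NF55 control. A rise in the controls may thus be part of being lowered at 6 weeks. From 2 to 6 weeks in TRDN hindlimbs, 28 of the 43 rose and 3 fell. Of the 22 raised probes, 14 fell and 5 rose. That comparison shares the TRDN 2 weeks arrays, from which part of these shifts may come. Of the 65, 45 changed in the same direction and 11 in the opposite direction in the 6-week comparison, which shares no arrays with the 2-week one. Independent lists would share 8.3 lowered probes where 28 were shared, and 5.2 raised probes where 17 were. In opposite directions, 10 lowered probes were raised at 6 weeks (10.2 if independent) and 1 raised probe was lowered (4.2). The comparisons share the spread estimate of each probe, so a probe with a small estimate is called more easily in both. The lists are therefore not independent. The count of 65 became 34 with median centring, 35 with no background subtraction and 269 with array weights, and it depended on single arrays. It was 42 without NF55 control replicate 1, 22 without replicate 2, 22 without TRDN 2 weeks replicate 1, 15 without replicate 2 and 29 without replicate 3. The 45 moved likewise, to 28, 19, 19, 12 and 26 without these arrays in turn, 22 with median centring, 23 with no background subtraction and 142 with array weights.

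Between the stages NF55 and NF66 the control hindlimbs changed at 11544 of 19932 probes, 5587 higher and 5957 lower. The median change over all probes was 0.0055 (log2). Loess centres each array, so the near-even split may come from the centring. Probe M19971_1241 (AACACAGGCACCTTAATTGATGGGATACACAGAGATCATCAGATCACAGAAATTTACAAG) rose by 9.74 on the log2 scale (SE 0.21, limma adjusted p = 1.59e-09, from 2 NF66 arrays with a value), and probe CB200461_411 (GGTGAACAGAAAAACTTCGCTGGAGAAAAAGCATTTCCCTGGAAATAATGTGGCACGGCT) by 9.15 (SE 0.19, limma adjusted p = 2.64e-10). Probe U41839_1558 changed by -6.35 (SE 0.32) and probe AB045599_2303 by -5.71 (SE 0.25), with limma adjusted p-values of 3.09e-07 and 5.52e-08, the first from 2 NF66 arrays with a value. At least 2-fold changes were found at 798 higher and 1539 lower probes, and at least 4-fold at 242 and 186. The balance of directions depended on the processing, with 6016 higher and 5622 lower from the scanner software's processed signals, 6015 and 5620 from the deposited ratios, and 5727 and 5700 at a normexp offset of 0.

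In TRDN hindlimbs, 4170 of 19962 probes changed between 2 and 6 weeks, 1788 higher and 2382 lower. The balance turned among larger changes, with 366 higher and 275 lower at 2-fold or more and 91 and 19 at 4-fold or more. Some of the probes with the largest normal rise also rose here. Probe M88105_736 (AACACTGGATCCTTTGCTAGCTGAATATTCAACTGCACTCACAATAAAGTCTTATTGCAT) went from -3.97 ± 0.20 to 4.16 ± 0.39 (log2 ratio, mean ± SD, n = 3), while NF66 control was at 4.97 ± 0.09. It was lower than NF66 control by 0.81 (SE 0.17, limma adjusted p = 0.00321) and rose by 0.93 less than between the control stages (SE 0.24, limma adjusted p = 0.0171). CB200461_411 rose by 7.92 (SE 0.19, limma adjusted p = 1.61e-09), with 1 of the 3 TRDN 2 weeks arrays not well above background. Probe AB045599_2303 changed by -4.58 (SE 0.25) and probe AF286646_897 by -3.57 (SE 0.13), with limma adjusted p-values of 9.67e-07 and 3.98e-08. With array weights in the fit, 6873 probes were called, and with median centring 29.3% of the calls were higher, against 42.9%.

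**Figure D2:**
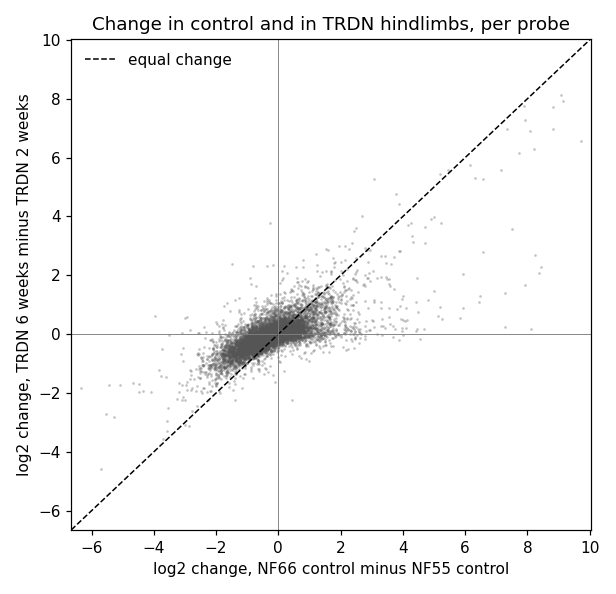
Log2 change of each probe in control hindlimbs (NF66 minus NF55, horizontal) and in TRDN hindlimbs (6 weeks minus 2 weeks, vertical), with a dashed line for equal change. The changes correlated at r = 0.733 across 19929 probes, and 77.1% of probes changed less in TRDN than in control hindlimbs in absolute value.

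The change in TRDN hindlimbs and the change between control stages share no arrays. They correlated at Pearson r = 0.733 and Spearman rho = 0.658 across 19929 probes, which are not independent replicates. Of the 797 probes at least 2-fold higher in NF66 than in NF55 that had values in all groups, 399 were also higher at 6 than at 2 weeks in TRDN hindlimbs and 7 were lower. For each probe the change in TRDN hindlimbs was taken as a percentage of the change between the control stages. The median of these percentages was 37.4% (SD 7.8 over the 3 TRDN 6 weeks arrays). For 465 of them the change in TRDN hindlimbs was smaller by the test of the difference, and 328 made under 25% of the normal rise while 175 made over 75%. Of the 1538 probes at least 2-fold lower in NF66, 1030 also fell in TRDN hindlimbs, the median was 42.9% (SD 3.4), and 1103 changed less than normally by the test of the difference. Both sets were chosen by the change between the control stages, which also enters the percentages and the test of the difference. Both measures therefore lean towards a smaller change in TRDN hindlimbs. With no fold cutoff the rising and falling medians were 28.8% and 38.4%, and at 4-fold or more 29.3% and 47.2%. At 2-fold or more, which median was larger depended on the processing. The rising and falling medians were 39.1% and 38.7% from the scanner software's processed signals and 39.6% and 38.7% from the deposited ratios. With no background subtraction they were 32% and 47.9%.

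At 6 weeks TRDN hindlimbs differed from NF66 control at 8545 of 19953 probes, 4715 higher and 3830 lower. The excess of higher probes depended on the processing, with 4647 higher and 4658 lower from the scanner software's processed signals and 4651 and 4659 from the deposited ratios. At 2-fold or more 729 were higher and 395 lower, and at 4-fold or more 57 and 125. A probe with one of the largest deficits rose between the control stages and was low in all tadpole groups. Probe BC054279_1562 (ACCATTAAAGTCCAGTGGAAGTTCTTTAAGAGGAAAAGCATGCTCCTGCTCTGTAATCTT) was at -4.26 ± 0.09 in TRDN 6 weeks and 3.60 ± 0.14 in NF66 control, with NF55 control at -4.52 ± 0.02 (log2 ratio, mean ± SD, n = 3), a difference of -7.86 (SE 0.07, limma adjusted p = 8.17e-13). Probe M11032_1827 (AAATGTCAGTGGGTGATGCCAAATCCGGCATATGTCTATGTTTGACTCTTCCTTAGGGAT) was higher by 4.73 (SE 0.17, limma adjusted p = 3.02e-08), standing at 0.18 ± 0.10 in TRDN 6 weeks and -4.55 ± 0.21 in NF66 control. Probe CF285494_119 (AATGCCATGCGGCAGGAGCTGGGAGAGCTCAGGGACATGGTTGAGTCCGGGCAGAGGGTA) was higher by 4.35 (SE 0.18, limma adjusted p = 9.4e-08). It was at 2.77 ± 0.26 in TRDN 6 weeks, above both TRDN 2 weeks at -1.02 ± 0.12 and NF66 control at -1.58 ± 0.13.

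CF285494_119 was among 607 probes that were higher at 6 weeks than both TRDN 2 weeks and NF66 control, while 89 were lower than both. At least 2-fold against both held for 61 and 3. These comparisons share the TRDN 6 weeks arrays. Simulated groups with no effect gave 0 such probes in each direction in 20 simulations, and independent lists would share 423 and 457.8. The first number leaves out real effects and the second the shared arrays, from which part of the overlap may come, so neither tells whether 607 or 89 is more than expected. With median centring the 607 became 311. The 89 became 59 with no background subtraction, 156 with array weights, 48 without TRDN 6 weeks replicate 3, and 53 and 54 without TRDN 2 weeks replicates 1 and 2.

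**Figure D3:**
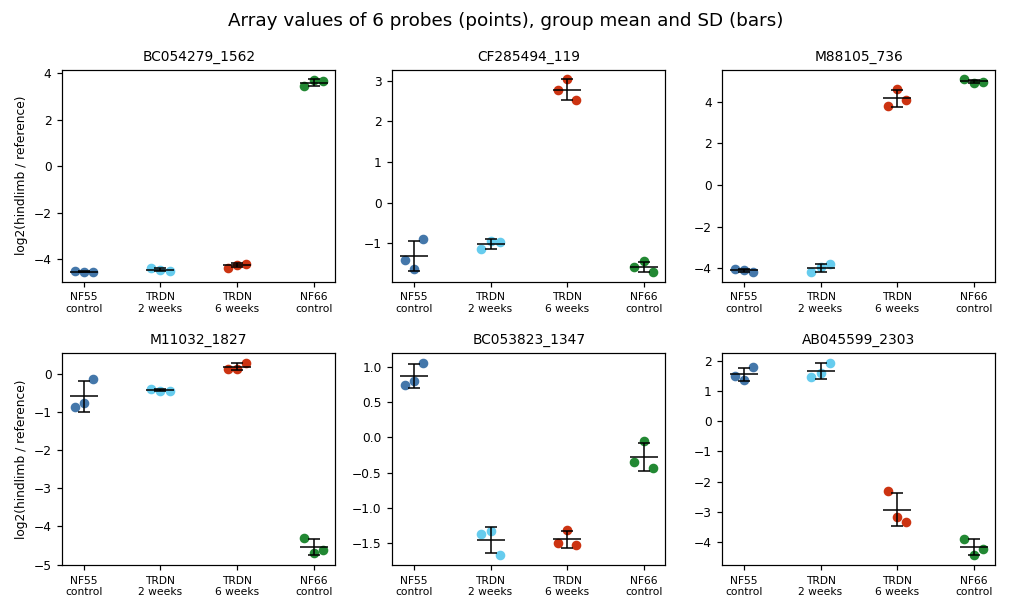
Log2 hindlimb over reference ratios of 6 probes, one point per array, with the group mean and SD as bars. BC054279_1562 stays near the tadpole value in TRDN 6 weeks, M88105_736 rises to 4.16, against 4.97 in NF66 control (adjusted p = 0.00321), and BC053823_1347 is at -1.45 and -1.44 in the TRDN groups.

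The transgene comparison at 6 weeks differed from that at 2 weeks at 4946 of 19929 probes, 2896 higher and 2050 lower, and at 4-fold or more 55 higher and 118 lower. The same test asks whether the change from 2 to 6 weeks in TRDN hindlimbs equalled that between the control stages. The difference was -7.94 (SE 0.10, limma adjusted p = 2.49e-11) for BC054279_1562. It was 4.57 (SE 0.24) for M11032_1827 and 4.52 (SE 0.42) for U41839_1558, with limma adjusted p-values of 1.5e-06 and 0.000119, the latter from 2 NF66 arrays with a value. Median centring gave 2761 probes, 75.1% of them higher against 58.6%, and Cy3 alone gave 3290.

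**Figure D4:**
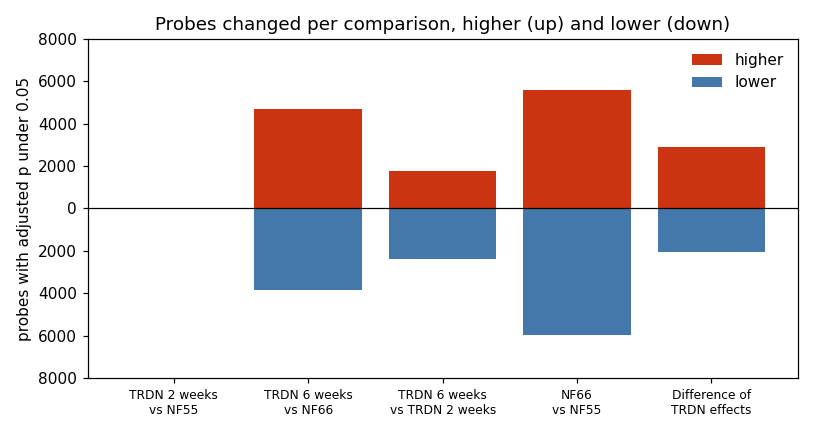
Number of probes with an adjusted p under 0.05 in each of the 5 comparisons, higher above the axis and lower below it. The bars run from 65 probes for TRDN 2 weeks against NF55 control, too few to see at this scale, to 11544 for NF66 against NF55 control.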

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

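The test of the reference channel was chosen only after its result was seen. The transgene effects at 2 and 6 weeks differed between the time points by the test of the difference itself at 4946 probes. The probes named for it had differences of 4.57 (M11032_1827), 4.52 (U41839_1558) and -7.94 (BC054279_1562) on the log2 scale. Of 100 relabellings of the arrays within the pairs of groups, the real one included, 9 gave as many probes, with up to 6794, so this count does not exclude chance. All 9 left the TRDN 6 weeks and NF66 arrays as 2 groups, and relabellings that mixed those arrays gave at most 1 probe, so the relabelling moved with the 6-week comparison and hardly tested the difference. The controls of the time points also differ in stage, NF55 and NF66, so a difference of transgene effects and a difference of controls stay open.

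The many probes that differed between TRDN 6 weeks and NF66 control were set against 4 technical explanations. The Cy5 reference channel alone called 17 probes, 0.2% of the 8545. In Cy5 1366 probes had an unadjusted limma p under 0.05, against 10075 with ratios. This argues against the reference as the source of most of the calls, while smaller differences in it stay open. In the brightest 25% of probes 67.0% were called, 156.5% of the share among all probes, so the calls were not confined to dim probes. The offset pulls dim ratios towards 0 and favours calls among bright probes, so this test decides no more about dim signal. After a correction for probe GC content, 93.9% of the called probes remained called in the same direction. Loess stays open as part of the count, since 64% of the probes remained called in the same direction with median centring, between the bounds set beforehand. The transgene, age, stage and length of doxycycline treatment stay among the open explanations, because the design does not separate them, as does slide order, which followed the groups.

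Splits of 3 arrays against 3 number 10, too few for a share under 0.05. The real split was the 1 with as many probes in each of 4 comparisons. For TRDN 2 weeks against NF55 control it gave 65 probes and the highest other 0. There 4 splits, the real one included, part all 3 same-numbered pairs and the other 6 part 1, and the 3 others that part as many pairs as the real one gave 0 probes too. For TRDN 6 weeks against NF66 control it gave 8545 and the highest other 1. For TRDN 6 weeks against 2 weeks it gave 4170 and the highest other 0, and for NF66 against NF55 control 11544 and the highest other 43.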

How the results depend on the processing

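The settings below were fixed before the data were examined, with 2 exceptions chosen after seeing the data. These were the fit without the NF55 control and TRDN 2 weeks arrays numbered 3 and the block in these 2 groups alone. For TRDN 2 weeks minus NF55 control (65 probes), the count was 35 with no background subtraction, 34 with median centring, 269 with array weights, 19 at an adjusted p under 0.01, 23 at 2-fold or more, and 24 without the arrays numbered 3. Leaving out each array in turn gave 15 to 79. For TRDN 6 weeks minus NF66 control (8545) it was 5628 at an adjusted p under 0.01 and 1124 at 2-fold or more, with 7057 to 8975 leaving out each array. For TRDN 6 weeks minus TRDN 2 weeks (4170) it was 6873 with array weights, 2405 at an adjusted p under 0.01 and 641 at 2-fold or more, with 2868 to 4617 leaving out each array. For NF66 minus NF55 control (11544) it was 2337 at 2-fold or more, with 10089 to 11421. For the difference of transgene effects (4946) it was 2761 with median centring, 3290 with Cy3 alone, 2501 at an adjusted p under 0.01 and 1014 at 2-fold or more, with 3877 to 5635. Stricter thresholds lower a count by construction, and for the other settings the cause was not tested. Other settings stayed within 1.5 times of the counts given, but a similar count did not mean the same probes. With only the groups compared, 51 probes were called at 2 weeks and 31 of the 65 were kept. For NF66 minus NF55 control, median centring called 10327 probes, kept 8138 of the 11544 and called 101 in the opposite direction. Cy3 alone called 8718, kept 7871 and called 43 in the opposite direction. Median centring called 14.7% of the 2-week probes as higher, against 33.8%, the processed signals and the deposited ratios 19.1%, at least 2-fold 8.7% and array weights 55.4%. Aquantile does not change ratios, and the series table comes from the processed signals, so neither is an independent check. Of the values of these last inputs, 1.6% differ by over 0.1 (log2), among them those of CB200461_411, which rose from 2 to 6 weeks by 10.125 with the processed signals and 8.894 with the series table, where ratios are cut at 100-fold. No named probe changed direction under any setting, and AF157558_1879 alone lost its call at the 0.05 threshold. The named probes were picked for the largest changes in these same data, so this tells nothing about the other calls.

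The replicate number as a block gave 46, 8285, 3966, 11232 and 4591 probes for the 5 comparisons in the order above. In NF55 control and TRDN 2 weeks alone, the block gave 46 too, with 41 of the 65 kept. It was fitted for the 2-week comparison only. Of the 4 probes named there it ended the call of AF157558_1879 (adjusted p 0.0625) and changed no other, and the block over all arrays ended no call of a named probe. Not run was a slide block, since no slide held more than 1 array. A scan block was not run either, since scan batches were not examined, nor were the gene list tests, since no probe could be named. Signal over background limits dim probes, since between 87.8% and 95.6% of probes per array were well above background in Cy3.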

Other observations

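The test of whether TRDN 6 weeks lies part way along the normal path was chosen only after its result was seen. TRDN 6 weeks arrays lay between the control stages on the first principal component. A candidate explanation is that they are part way along the normal path. At 696 probes they lay beyond both the 2-week and the NF66 values, among 2554 probes called in both comparisons. The bound set for this test was wrong for this design, since it left out that the comparisons share the TRDN 6 weeks arrays, and since a normal peak between NF55 and NF66 would give the same values and no control stage between them was sampled, so the explanation stays open. A further hypothesis, that the probes that failed to rise were those already lowered at 2 weeks, was not decided. Its test gave an odds ratio of 1.31 (Fisher's exact p = 0.654, two-sided) but used the TRDN 2 weeks and NF55 arrays on both sides, and a low TRDN 2 weeks value by itself enlarges the later rise, so it tells nothing for or against.

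The arrays numbered 3 of NF55 control and TRDN 2 weeks deviated together from the other arrays of their groups, at r = 0.324 across probes, as did those numbered 1 at 0.35 and those numbered 2 at 0.202. RNA of NF66-like limbs mixed into both samples is argued against, since the 24 probes at least 64-fold higher in NF66 had median deviations of -0.036 and 0.113 (log2). A trend on probe GC content is argued against too, since 102.5% of the correlation was left without it. Small differences in developmental stage may account for part of it, since the deviations correlated at 0.265 and 0.342 with the change from tadpole to NF66 measured on other arrays. The labels give both samples the stage NF55, and no other measure of stage was available to test this.

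The Cy5 reference channel alone called 8 probes between TRDN 2 weeks and NF55 control, 12.31% as many as the 65 called with ratios, with 1 in both. It called 17 between TRDN 6 weeks and NF66 control, of which 12 were called with ratios too. It called 41 between TRDN 6 and 2 weeks, 16 of them with ratios too, and 59 between the control stages, 49 of them with ratios too. The same reference was used on every array. Cy5 probes with an unadjusted limma p under 0.05 numbered 2486, 1366, 2529 and 1837 in these comparisons in turn. In the first of them the ratios had 1198 such probes, so a difference in the reference stays open for the 2-week comparison. Among pairs of different probes of 1 accession, 38 of the 39 pairs called together in the 6-week comparison had the same direction. In 29 more of the 88 pairs only 1 probe was called, and the changes of the pairs differed with an SD of 0.482 (log2).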
